A study of Homo sapiens with 10 samples.

How the data were processed

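RNA was extracted from HS-SY-II cells treated with 100 nM WA-68 for 12, 24, 48 or 96 h or with DMSO, with 2 biological replicates in each of 5 groups and 10 libraries in all. Per the labels the libraries were stranded poly(A) mRNA libraries, sequenced as paired ends on a NovaSeq X. The submitters' processing notes name bcl2fastq for base calls, FastQC for quality, Trim Galore with cutadapt for trimming, STAR for alignment to GRCh38 and featureCounts for counting. Their versions, the annotation release, the strand setting and the handling of multiply mapped reads are not given in the sources used here. The deposited table holds the raw read count of each of 63140 gene identifiers in each library, as whole numbers with no normalization. All per-sample columns were used, and 62541 identifiers have a symbol in the gene name table used here.

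Total counts per library ran from 7349744 to 13200051, with 32684 genes holding at least 1 count. Read totals before assignment to genes were not analysed here, so the depth given is that of assigned counts. Genes were tested where edgeR's filterByExpr kept them by group, which left 16382. Library sizes were scaled by the trimmed mean of M values (TMM), and levels are TMM-scaled counts in CPM. Genome positions come from GENCODE annotation of GRCh38 and not from the release used for counting.

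The model had 1 mean per group and no other term, fitted to all 10 libraries in edgeR 4.0.16 under R 4.3.3, with a quasi-likelihood F test. It had 5 residual degrees of freedom, 18.5 prior degrees of freedom and a common biological coefficient of variation of 7.17%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The standard error of a log2 fold change was taken as its size over the square root of F. The comparisons were each of the 4 times against DMSO, each time against the one before, and 96 h against 12 h, with a joint test of the 4 times. Every comparison against DMSO uses the same 2 DMSO libraries, which were not split because each part would hold 1. Correlations of fold changes between times were therefore set against 20 simulated data sets with no treatment effect and the same shared controls. In a comparison of 2 libraries with 2 no regrouping can give a share under 0.05. No regroupings were counted, for these comparisons or for the joint test.

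The comparisons, 36 gene lists, the rule for named genes and most alternatives were set before the data were examined. The lists covered BAF subunits, Polycomb subunits, BRD family and BET response markers, E3 ligase parts, synovial sarcoma associated genes, homeobox and T-box factors, cancer-testis antigens, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and D-type cyclins, p53 targets, and the BCL2 family. They further covered MYC and ribosome biogenesis, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, mitochondrially encoded transcripts, interferon response, MHC class I, inflammatory factors, cholesterol, the unfolded protein and integrated stress response, heat shock, and hypoxia and glycolysis. The remaining lists covered extracellular matrix and mesenchymal genes, TGF-beta with YAP and serum response, epithelial markers, Wnt, FGF and ERK, Notch and Hedgehog, neuronal, osteochondrogenic, adipogenic, myogenic, endothelial and leukocyte genes, and lysosome and autophagy. Some genes sit in more than 1 list, MYC in both its own list and the Wnt list. Lists with at least 3 measured genes, 33 of 36, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Each list was also tested with an estimated correlation and with fry, which does not compare a list with other genes. camera called 9, 10, 10 and 11 of the 33 lists at 12, 24, 48 and 96 h against DMSO and 15 at 96 h against 12 h. It called 0 of them in these 5 comparisons with an estimated correlation, and fry called 5, 9, 11, 15 and 11.

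The text names BRD9, BICRA, BICRAL, SS18 and SSX1 throughout. For each time against DMSO it takes the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 5 CPM and both treated libraries beyond both DMSO libraries. For 96 h against 12 h it takes 5 each way. From each list it takes up to 4 members with the smallest adjusted p, or 2 of the most abundant where none was called. From the genes so chosen, the text gives mainly those that kept their call without each library in turn. Not every gene that the rule names is reported here.

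Alternatives set beforehand were other scalings (RLE factors, upper-quartile factors, library size only), no filter, a stricter filter of 5 CPM in 2 libraries, a term for replicate number, only the 4 libraries compared, and each library left out in turn. Further ones were DESeq2 1.42.0, limma-voom, a log2 fold change of at least 1, an adjusted p under 0.01, glmTreat against 1.5-fold, fry and the estimated correlation. Added after the data were seen were an offset for transcript GC content, an offset for transcript length, and leaving out replicate 2 of DMSO and of 96 h together. Each offset was a spline of a library's log2 CPM deviation on GC content or log2 length, for the 95.8% of tested genes with a transcript in the annotation. GC content and length were those of the longest annotated transcript of a gene.

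The pipeline was tested on simulated data for 96 h against DMSO with all 16382 genes, over 5 draws with 200 changed genes each. It recovered 13.2% of genes changed 1.25-fold, 59.8% at 1.5-fold, 78.0% at 2-fold and 93.0% at 4-fold, and 5.15% of its calls were false. These draws gave all groups the same dispersion for each gene and held no GC trend. The real DMSO and 96 h replicates differed more than those of the other groups, so these shares do not cover the real 96 h comparison. camera called a shifted list in 5 of 5 draws and 1.25% of the other lists. The simulated genes were drawn independently of each other, so the 1.25% does not cover lists whose members vary together. An added GC trend raised the coefficient of variation from 7.02% to 13.2%, and the offset returned it to 7.02%. Small changes were often missed in these simulated data. No library was left out of the reported fit.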

Results

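Poly(A) RNA was sequenced from HS-SY-II, an established human synovial sarcoma cell line. Cells were kept with 100 nM WA-68, a degrader directed at the bromodomain protein BRD9, for 12, 24, 48 or 96 h, or with the DMSO vehicle. Each of the 5 groups held 2 biological replicates, 10 libraries in all, and the labels give no harvest time for the DMSO cultures. Counts assigned to genes came to 13200051 and 8830910 in replicates 1 and 2 of DMSO. They came to 8900937 and 8556353 at 12 h, 7931031 and 10136473 at 24 h, 8680831 and 7982460 at 48 h, and 10401147 and 7349744 at 96 h. Of 63140 gene identifiers, 16382 held enough counts to be tested. Levels are given in CPM, counts scaled to a common library size, as mean ± SD with n = 2 per group. Changes are log2 fold changes from edgeR with their standard error (SE). The p-values of single genes rest on the spread between labelled biological replicates of a single cell line, pooled over all 5 groups and moderated across genes. Those of camera set a list against the other genes, and those of the test of neighbouring genes come from calls permuted across genes. Both take genes and not replicates as the unit. Between the replicates of a group the Pearson correlation of log2 CPM across genes ran from 0.989 to 0.991, and genes are not independent replicates. The replicate spread was still unequal between groups. A chi-square per gene of replicate counts against Poisson sampling, not corrected for depth, was 6.89 in DMSO and 9.48 at 96 h. It was 2.20, 2.17 and 2.66 at 12, 24 and 48 h. The pooled spread is therefore not that of the groups compared.

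Replicate 2 of DMSO and replicate 2 of 96 h stood apart from the other libraries. They lay at -24.2 and -26.0 on the second principal component, which held 16.4% of the variance, while the other 8 libraries lay between -0.71 and 14.4. Within DMSO the log2 difference of replicate 2 from replicate 1 increased with the GC content of the transcript (Spearman correlation across genes 0.571), and within 96 h the correlation was 0.289. It was -0.059 at 12 h, -0.167 at 24 h and -0.292 at 48 h. Mitochondrial transcripts took 10.9% of the counts in replicate 2 of 96 h and 6.79% to 8.75% in the other 9 libraries.

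**Figure D1:**
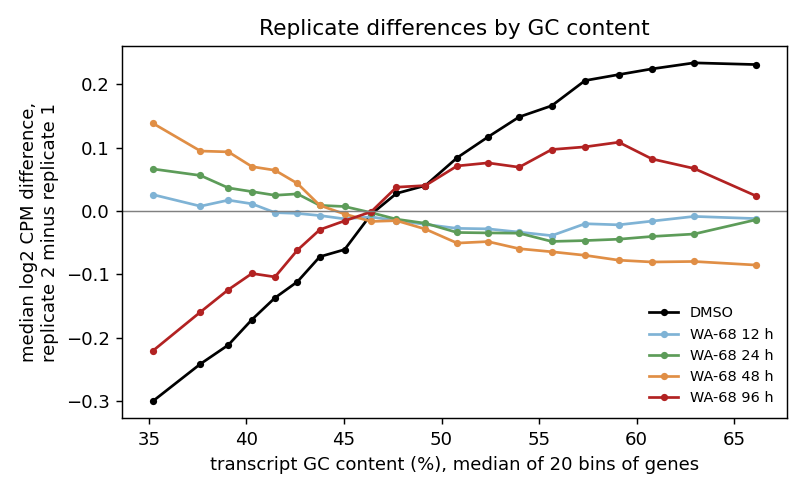
Median log2 CPM difference of replicate 2 from replicate 1 (vertical axis) in 20 bins of transcript GC content in percent (horizontal axis), with 1 line per group. The DMSO line climbs with GC content (Spearman correlation across genes 0.571), as does the 96 h line (0.289), while the 48 h line declines (-0.292).

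The transcript of BRD9 was examined to see whether the gene of the targeted protein responded, and protein levels were not analysed here. BRD9 (ENSG00000028310, GRCh38 chromosome 5, 850291 to 892824), the bromodomain subunit of the non-canonical BAF chromatin remodelling complex (ncBAF), stood at 104.1 ± 5.61 CPM in DMSO. It stood at 94.2 ± 1.95 CPM at 12 h, 94.98 ± 1.90 at 24 h, 92.9 ± 1.67 at 48 h and 88.7 CPM at 96 h. None of the 4 differences passed the edgeR test, with adjusted p = 0.479, 0.502, 0.29 and 0.0935 and log2 fold changes of -0.14, -0.13, -0.16 and -0.23. BICRAL (ENSG00000112624), a scaffold subunit of ncBAF, rose from 78.6 ± 0.26 CPM in DMSO to 109, 102, 105 and 108 CPM at 12, 24, 48 and 96 h. Its log2 fold changes were 0.47, 0.37, 0.42 and 0.46, each with an SE of 0.091 (adjusted p = 0.00383, 0.0224, 0.00479 and 0.00126). SS18, the fusion partner in synovial sarcoma, stood at 234.8 ± 13.4 CPM in DMSO, and SSX1 stood at 52.1 ± 3.67 CPM. Neither passed the test at any time against DMSO, nor did BICRA. SSX1 was called higher at 96 h than at 12 h (log2 fold change 0.36, SE 0.10, adjusted p = 0.0451), a call lost when any 1 of the 8 WA-68 libraries was left out. Reads of SS18, SSX1 and the SS18-SSX fusion cannot be separated in a gene count, and SSX paralogs share sequence. The BICRAL call was lost at 12 h without replicate 1 (adjusted p = 0.0563) or replicate 2 (0.0895) of 12 h. It was lost at 24 h without replicate 1 (0.219) or replicate 2 (0.177) of 24 h and at 48 h without replicate 1 of 48 h (0.0888), and it held at 96 h without any library.

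Within the wider list of 26 measured BAF subunits, 1 gene rose at 12 h and 1 at 24 h, the same gene, BICRAL, in both. At 48 h 1 rose and 2 fell, and at 96 h 2 rose and 2 fell (2 and 2 adjusted over the list alone). The median log2 fold change at 96 h was 0.093, and camera did not call the list at any time (adjusted p = 0.377, 0.618, 0.142 and 0.494). Among 13 genes for E3 ligase parts, the machinery that degraders recruit, 1 fell at 96 h (1 adjusted over the list alone) with a list median of -0.135 (camera adjusted p = 0.0979). Among 14 BRD family and BET response genes, 2 rose at 96 h (4 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0672).

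**Figure D2:**
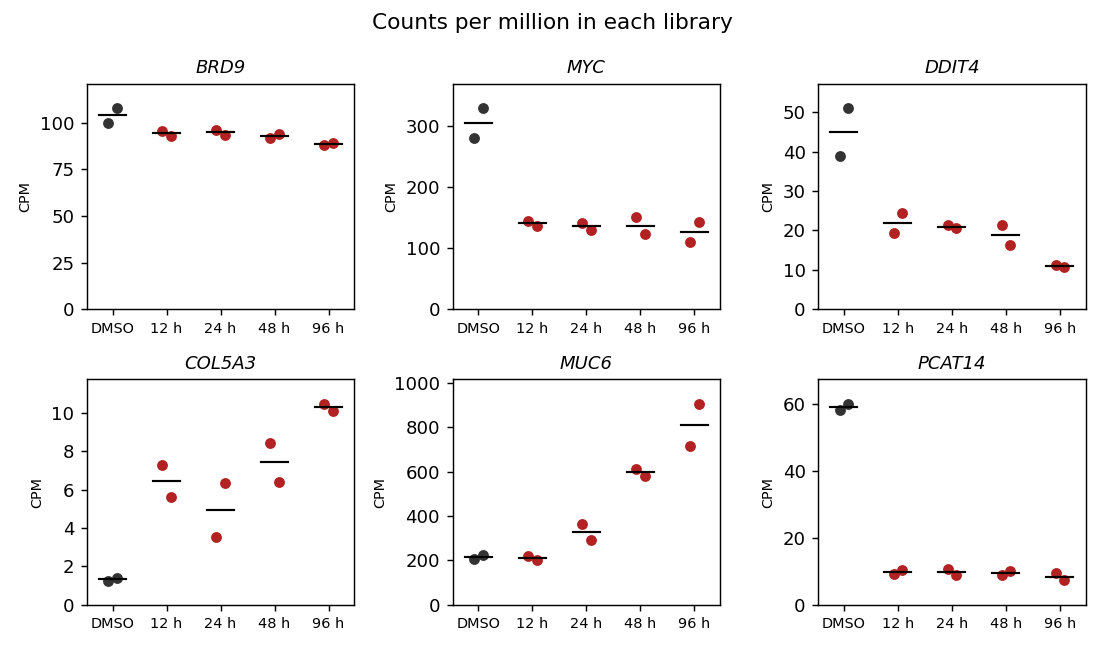
CPM (vertical axes, from 0) of BRD9, MYC, DDIT4, COL5A3, MUC6 and PCAT14 in each library (points), with the group mean as a bar, for DMSO and 12, 24, 48 and 96 h of WA-68. MUC6 means climb from 214 CPM in DMSO to 811 CPM at 96 h, while PCAT14 means drop from 59.01 to 8.40 CPM and BRD9 means stay between 88.7 and 104.1 CPM.

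The 12 h comparison asked which transcripts respond first. After 12 h of WA-68 the long non-coding RNA PCAT14 (ENSG00000280623, chromosome 22, 23536881 to 23547797) fell 6.01-fold, from 59.01 ± 1.46 to 9.81 ± 0.75 CPM (log2 fold change -2.59, SE 0.14, adjusted p = 1.65e-11). CCDC26 (ENSG00000229140, chromosome 8, 128634199 to 129683679), another long non-coding RNA, fell 4.68-fold, from 27.18 ± 2.999 to 5.85 ± 0.83 CPM (adjusted p = 3.9e-08). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), a transcription factor that drives growth and ribosome production, fell 2.17-fold from 305 ± 34.9 to 141 ± 5.63 CPM (log2 fold change -1.12, SE 0.12, adjusted p = 4.93e-06). COL5A3 (ENSG00000080573, chromosome 19, 9959561 to 10010471), a fibrillar collagen chain, rose 4.87-fold from 1.33 ± 0.12 to 6.45 ± 1.16 CPM (log2 fold change 2.28, SE 0.32, adjusted p = 0.000162). In all, edgeR called 201 genes higher and 315 lower at 12 h than in DMSO, 3.15% of those tested, of which 33 and 37 changed at least 2-fold.

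UNC80, a subunit of a sodium leak channel, rose by 1.42 on the log2 scale at 12 h (SE 0.20), the sodium channel SCN9A by 1.19 (SE 0.19) and MAP2, a microtubule protein of neurons, by 0.80 (SE 0.099). RASGEF1B, an exchange factor for Ras-family GTPases, rose by 1.16 (SE 0.14), RPS6KL1 by 1.29 (SE 0.21) and the non-coding RNA LNC-LBCS by 1.17 (SE 0.18). The adjusted p of these 6 ran from 2.1e-05 for RASGEF1B to 0.000669 for RPS6KL1. Among the genes that fell were SEZ6 (log2 fold change -1.60, SE 0.19), a membrane protein of neurons, the adhesion molecule KIRREL3 (-1.54, SE 0.21), the secreted kinase PKDCC (-1.17, SE 0.10) and the matrix proteoglycan BGN (-1.16, SE 0.17). The non-coding LINC01659, close to PCAT14 on chromosome 22, fell by 1.29 (SE 0.19). DDIT4, an inhibitor of mTORC1, fell from 45.1 ± 8.66 to 21.9 ± 3.63 CPM (adjusted p = 0.000173), and SCD, the stearoyl-CoA desaturase, fell from 2268 ± 64.9 to 1271 ± 200.2 CPM (adjusted p = 1.07e-05). The cyclin CCND2 (log2 fold change -0.79), the T-box factor TBX2 (-0.76) and the ETS factor ETV4 (-0.74) fell as well, with adjusted p = 5.62e-06, 0.000195 and 0.000332. All genes named in this paragraph and the 4 leading genes kept their call when any library was left out. Of all 66 genes called at 12 h among those chosen for naming, 24 kept it and 42 lost it without at least 1 library.

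By fixed gene list, 12 of 27 measured genes of MYC and ribosome biogenesis fell at 12 h (21 adjusted over the list alone), with a median log2 fold change of -0.35. Besides MYC they included MYBBP1A, a nucleolar protein (-0.61, SE 0.095, adjusted p = 0.000512). camera gave adjusted p = 9.3e-14 for the list, and adjusted p = 0.134 with an estimated correlation. In the lysosome and autophagy list 7 of 22 rose (12 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 5.11e-09, and adjusted p = 0.208 with an estimated correlation). NEU1, a lysosomal sialidase, rose 1.65-fold (log2 fold change 0.72, SE 0.11, adjusted p = 0.000274). Of 23 hypoxia and glycolysis genes 5 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00306, and adjusted p = 0.542 with an estimated correlation). The gene that rose was NDRG1 (log2 fold change 0.81, SE 0.11, adjusted p = 0.000124). Of 18 Wnt targets and inhibitors 4 fell (6 adjusted over the list alone), MYC and the inhibitor NKD2 (-0.58, SE 0.096) among them, with a median of -0.18 (camera adjusted p = 0.000192, and adjusted p = 0.359 with an estimated correlation). Of 20 interferon genes 3 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.0018, and adjusted p = 0.175 with an estimated correlation).

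A further 4 lists were called lower at 12 h with few called members. Of 62 ribosomal protein genes 1 fell (0 adjusted over the list alone), with a median of -0.145 (camera adjusted p = 7.01e-07, and adjusted p = 0.542 with an estimated correlation). Of 23 stress response genes 2 fell (3 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0449, and adjusted p = 0.542 with an estimated correlation). Among 13 mitochondrially encoded transcripts edgeR called 0, with 8 at an unadjusted p under 0.05, 7 lower adjusted over the list alone and 0 by DESeq2 and limma-voom. Their median was -0.30 (camera adjusted p = 0.00306, and adjusted p = 0.598 with an estimated correlation). Among 24 cholesterol genes edgeR called 0, with 7 at an unadjusted p under 0.05, 1 higher and 3 lower adjusted over the list alone and 0 by DESeq2 and limma-voom. Their median was -0.19 (camera adjusted p = 0.00306, and adjusted p = 0.542 with an estimated correlation).

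Of the genes called at 12 h 39% were higher, and 62.4% with library size as the only scaling, which gave 173 lower genes and moved the median of all genes from -0.0021 to 0.062. Counts fell to 34 higher and 68 lower without replicate 1 of 12 h, and to 58 and 74 without replicate 2. They came to 533 lower genes without replicate 1 of DMSO, to 120 higher genes with DESeq2, and to 483 and 781 with an offset for GC content, which was chosen after the data were seen.

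The 24 h comparison asked how far the response had gone after a day. PCAT14 stood at 9.90 ± 1.27 CPM (log2 fold change against DMSO -2.58, SE 0.14, adjusted p = 1.56e-11), CCDC26 at 5.25 ± 0.92 CPM (-2.40, SE 0.18) and MYC at 136 ± 8.52 CPM (-1.17, SE 0.12, adjusted p = 2.75e-06). SEZ6 (-1.93, SE 0.20), KIRREL3 (-1.93, SE 0.22), PKDCC (-1.29, SE 0.10), BGN (-1.15, SE 0.17) and LINC01659 (-1.34, SE 0.19) were lower again. Falls that ranked among the 8 largest at 24 h also took in DDN, a protein of dendrites and podocytes (-1.28, SE 0.17, adjusted p = 0.000109), and DUSP9, a phosphatase of MAP kinases (-1.28, SE 0.18, adjusted p = 0.000208). BMP3, a bone morphogenetic protein, rose 2.72-fold (log2 fold change 1.44, SE 0.22, adjusted p = 0.000414), UNC80 2.52-fold and LNC-LBCS 2.39-fold. MAP2 stood at 64.8 ± 2.82 CPM against 34.1 ± 0.36 in DMSO (log2 fold change 0.92, SE 0.098, adjusted p = 4.06e-06). The bHLH factor SIM2 fell by 0.74 (SE 0.11) and ANKRD1, a target of YAP, fell by 1.95 (SE 0.29, adjusted p = 0.000287). SNAI2, a mesenchymal transcription factor, fell by 0.57 (SE 0.097), DDIT4 by 1.09 (SE 0.15) and CCND2 by 0.77 (SE 0.084). The genes given here kept their call when any library was left out, as did 21 of the 76 called at 24 h among those chosen for naming, while 55 lost it without at least 1. edgeR called 220 genes higher and 369 lower, 3.6% of those tested.

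Of the ribosomal protein genes 25 of 62 fell at 24 h (59 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 3.49e-24, and adjusted p = 0.299 with an estimated correlation). Of the MYC and ribosome biogenesis genes 13 of 27 fell (23 adjusted over the list alone), NOLC1 by 0.52 (SE 0.089), with a median of -0.405 (camera adjusted p = 4.82e-16, and adjusted p = 0.0999 with an estimated correlation). Of the lysosome and autophagy genes 5 of 22 rose (12 adjusted over the list alone), the protease CTSA by 0.50 (SE 0.091), with a median of 0.27 (camera adjusted p = 8.87e-08, and adjusted p = 0.285 with an estimated correlation). Of the G1/S and DNA replication genes 3 of 32 fell (11 adjusted over the list alone), with a median of -0.195 (camera adjusted p = 4.86e-06, and adjusted p = 0.423 with an estimated correlation). Among the 30 G2/M genes edgeR called 0 (0 adjusted over the list alone), with 7 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Their median was 0.16 (camera adjusted p = 0.000148, and adjusted p = 0.315 with an estimated correlation). Hypoxia and glycolysis genes fell in 7 cases of 23 and rose in 1 (14 and 2 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.000136, and adjusted p = 0.423 with an estimated correlation).

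Of the interferon genes 2 rose and 1 fell at 24 h (7 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00247, and adjusted p = 0.229 with an estimated correlation). Of the stress response genes 3 of 23 fell (4 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.000654, and adjusted p = 0.299 with an estimated correlation). Of 8 epithelial markers 2 rose (3 adjusted over the list alone and 0 with DESeq2), with a median of 0.31 (camera adjusted p = 0.0256, and adjusted p = 0.423 with an estimated correlation). Of the Wnt genes 4 of 18 fell (4 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00206, and adjusted p = 0.368 with an estimated correlation). Of the genes called at 24 h 37.4% were higher, and 59.5% with library size as the only scaling, which gave 205 lower genes. Counts fell to 47 higher and 89 lower without replicate 1 of 24 h and to 45 and 67 without replicate 2. Lower genes came to 636 without replicate 1 of DMSO and 243 without replicate 2 of 12 h, while the 4 libraries fitted alone gave 108 and 180, DESeq2 gave 123 higher genes, and the GC offset gave 504 and 912.

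The 48 h comparison covered a longer exposure, and in it genes of DNA replication and of mitosis were lower. Of 32 G1/S and replication genes 21 fell (28 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 1.87e-14, and adjusted p = 0.236 with an estimated correlation). They included the helicase subunits MCM4, from 535.9 ± 1.62 to 378.9 ± 6.98 CPM, and MCM7, from 394 ± 40.3 to 269 ± 21.9 CPM, with log2 fold changes of -0.50 (SE 0.086) and -0.55 (SE 0.097). The licensing factor CDT1 fell by 0.68 (SE 0.12, adjusted p = 0.000974) and UHRF1, which maintains DNA methylation, by 0.53 (SE 0.094, adjusted p = 0.000931). Of 30 G2/M genes 19 fell (23 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 1.56e-11, and adjusted p = 0.15 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell by 0.57 (SE 0.11, adjusted p = 0.00137).

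In total 657 genes were higher and 882 lower at 48 h than in DMSO by edgeR, 9.39% of those tested. MUC6 (ENSG00000184956, chromosome 11, 1012821 to 1036706), a secreted mucin, rose 2.79-fold from 214 ± 11.9 to 596 ± 23.5 CPM (log2 fold change 1.48, SE 0.11, adjusted p = 8.11e-09). NGFR, the low-affinity neurotrophin receptor, rose 3.42-fold (log2 fold change 1.77, SE 0.27). COL5A3 rose 5.62-fold and PRR36 3.02-fold, and MAP2 stood at 82.8 ± 0.62 CPM (log2 fold change 1.28, SE 0.097, adjusted p = 1.06e-08). TM7SF2, a sterol reductase, rose 2.23-fold (1.16, SE 0.16), and PHLDA1, a target of ERK signalling, by 0.53 (SE 0.099). PCAT14 stood 6.204-fold below DMSO, CCDC26 3.98-fold, SEZ6 3.38-fold, KIRREL3 3.33-fold and PKDCC 3.05-fold (adjusted p from 1.54e-11 for PCAT14 to 1.77e-05 for KIRREL3). The scavenger receptor SCARA5 fell by 1.24 (SE 0.13), the acid-sensing channel ASIC4 by 1.29 (SE 0.19), SIM2 by 0.92 (SE 0.11) and the homeobox factor UNCX by 0.94 (SE 0.16).

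Of the MYC and ribosome biogenesis list 20 of 27 fell at 48 h (26 adjusted over the list alone), RRP12 by 0.55 (SE 0.096), with a median of -0.44 (camera adjusted p = 5.75e-15, and adjusted p = 0.117 with an estimated correlation). Of the ribosomal protein genes 46 of 62 fell (59 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 7.54e-21, and adjusted p = 0.269 with an estimated correlation). Of the hypoxia and glycolysis genes 11 of 23 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 6.79e-05, and adjusted p = 0.41 with an estimated correlation). The glycolytic enzymes ENO1, LDHA, PGK1 and HK2 fell by 0.70, 0.61, 0.54 and 0.84 (SE 0.090, 0.084, 0.084 and 0.13). Of the lysosome and autophagy genes 9 of 22 rose (14 adjusted over the list alone), CTSA by 0.53 (SE 0.091) and the sterol carrier NPC2 by 0.53 (SE 0.095), with a median of 0.25 (camera adjusted p = 4.38e-06, and adjusted p = 0.236 with an estimated correlation). Of the extracellular matrix and mesenchymal list edgeR called 8 of 28 genes, and camera did not call the list. Its members moved in both directions. SNAI2, BGN and PDGFRA fell by 0.64, 1.07 and 0.60 (SE 0.097, 0.17 and 0.11). COL5A2 stood at 61.01 and 65.62 CPM at 48 h against 45.16 and 48.58 CPM in DMSO.

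Another 4 lists were called at 48 h. Of 37 respiratory chain genes 2 fell (0 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00334, and adjusted p = 0.43 with an estimated correlation). Of the interferon genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00601, and adjusted p = 0.196 with an estimated correlation). Of the epithelial markers 3 of 8 rose (4 adjusted over the list alone and 0 with DESeq2), with a median of 0.63 (camera adjusted p = 0.01, and adjusted p = 0.395 with an estimated correlation). Of 8 neuronal genes 2 rose (3 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 0.0132, and adjusted p = 0.236 with an estimated correlation). Of the genes called at 48 h 42.7% were higher, 55.7% with upper-quartile scaling and 60.3% with library size alone, which gave 543 lower genes. Counts fell to 269 higher and 395 lower without replicate 1 of 48 h and to 256 and 164 without replicate 2; the 4 libraries fitted alone gave 462 lower genes, DESeq2 398 higher genes and the GC offset 1628 lower genes.

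At 96 h, the longest exposure, COL5A3 stood at 10.3 ± 0.27 CPM against 1.33 ± 0.12 in DMSO, a 7.78-fold rise (log2 fold change 2.96, SE 0.29, adjusted p = 3.97e-07). MUC6 reached 811 ± 135 CPM (1.92, SE 0.11, adjusted p = 5.56e-11), and PRR36 (2.51, SE 0.24), NGFR (2.44, SE 0.25) and the matrix protein MATN2 (1.98, SE 0.16) rose at least 3.93-fold each. CCDC26 fell 8.21-fold to 3.35 ± 0.23 CPM (log2 fold change -3.04, SE 0.19, adjusted p = 2.9e-10) and PCAT14 6.89-fold (-2.79, SE 0.14). DDIT4 (ENSG00000168209, chromosome 10, 72273920 to 72276036) fell 4.02-fold (-2.01, SE 0.16, adjusted p = 1.21e-08). ASIC4 fell by 1.99 (SE 0.21), DDN by 1.67 (SE 0.18), SIM2 by 1.56 (SE 0.12), MYC by 1.28 (SE 0.12) and SCD by 0.91 (SE 0.094). edgeR called 1006 genes higher and 1123 lower, 13.0% of those tested, of which 210 and 94 changed at least 2-fold.

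**Figure D3:**
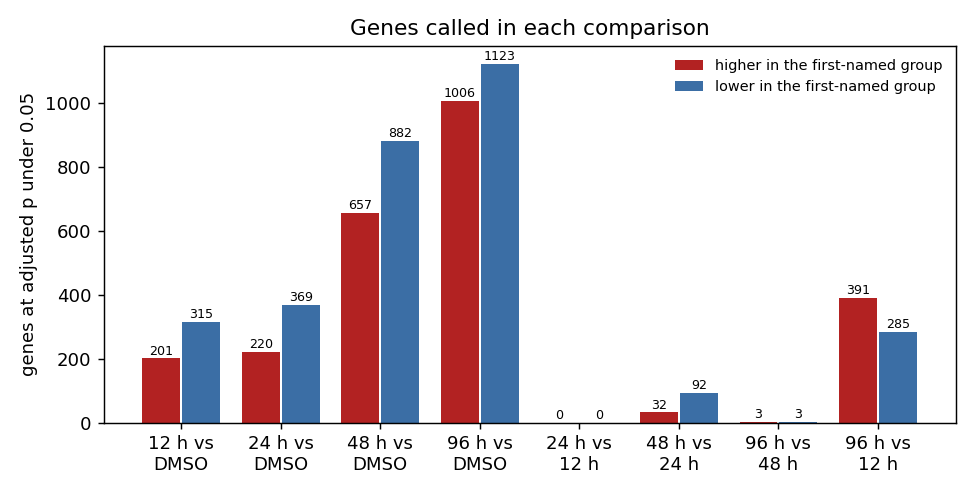
Number of genes called by edgeR (vertical axis) as higher or lower (bars) in each of the 8 comparisons, 4 against DMSO and 4 between times. Against DMSO the bars grow from 201 higher and 315 lower at 12 h to 1006 and 1123 at 96 h, while 96 h against 48 h shows 3 and 3.

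Of the cytosolic ribosomal protein genes 57 of 62 fell at 96 h (59 adjusted over the list alone), with a median log2 fold change of -0.51. RPS18 fell from 1016 ± 33.3 to 601 ± 6.84 CPM (-0.76, SE 0.079, adjusted p = 6.52e-07), RPL13A from 1275 ± 38.8 to 812 CPM (-0.65, SE 0.079) and RPL4 from 1482 ± 28.0 to 973 ± 51.9 CPM (-0.61, SE 0.078). camera gave adjusted p = 3.79e-31 for the list, and adjusted p = 0.186 with an estimated correlation. Processed pseudogenes share sequence with these genes, and the handling of multiply mapped reads is not given in the sources used here. Of the MYC and ribosome biogenesis genes 20 of 27 fell (27 adjusted over the list alone), BOP1 by 0.58 (SE 0.099) and NOLC1 by 0.51 (SE 0.089), with a median of -0.44 (camera adjusted p = 2.22e-13, and adjusted p = 0.149 with an estimated correlation). Of 37 nuclear genes of the respiratory chain 4 fell (12 adjusted over the list alone), ATP5F1B by 0.45 (SE 0.085), with a median of -0.23 (camera adjusted p = 1.46e-06, and adjusted p = 0.186 with an estimated correlation).

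Hypoxia and glycolysis genes had the lowest median of the 36 lists at 96 h, -0.73, with 17 of 23 lower and 1 higher (17 and 4 adjusted over the list alone). It was called (camera adjusted p = 3.92e-07, and adjusted p = 0.251 with an estimated correlation). ENO1 fell from 636.8 ± 64.3 to 338 ± 11.6 CPM (log2 fold change -0.91, SE 0.090, adjusted p = 3.48e-07), LDHA from 514.5 ± 5.23 to 296 ± 1.92 CPM (-0.80, SE 0.084) and PGK1 from 459.7 ± 29.4 to 263 ± 1.17 CPM (-0.81, SE 0.084). HK2, which starts glycolysis, fell by 1.10 (SE 0.14). Of the G1/S genes 14 of 32 fell (17 adjusted over the list alone), MCM2 by 0.55 (SE 0.098), with a median of -0.26 (camera adjusted p = 2.92e-07, and adjusted p = 0.36 with an estimated correlation). Of the G2/M genes 7 of 30 fell (9 adjusted over the list alone), AURKA by 0.36 (SE 0.090), with a median of -0.22 (camera adjusted p = 1.05e-05, and adjusted p = 0.186 with an estimated correlation). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 18.4 ± 0.40 to 29.04 ± 0.41 CPM (0.66, SE 0.13, adjusted p = 0.0011), and CCND2 fell by 0.81 (SE 0.084).

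Among the lists called higher at 96 h, 4 of 8 epithelial markers rose (5 adjusted over the list alone and 1 with DESeq2), with a median of 0.90 (camera adjusted p = 7.81e-05, and adjusted p = 0.186 with an estimated correlation). OCLN, a tight junction protein, rose from 2.62 ± 0.36 to 7.28 ± 0.57 CPM (1.46, SE 0.25, adjusted p = 0.000244). Of 19 TGF-beta, YAP and serum response genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00598, and adjusted p = 0.365 with an estimated correlation). AMOTL2 rose by 0.70 (SE 0.099), CCN2 by 1.13 (SE 0.22) and ID1 by 0.59 (SE 0.10), while ANKRD1 fell by 2.01 (SE 0.29). Of the lysosome and autophagy genes 8 of 22 rose (12 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.00011, and adjusted p = 0.262 with an estimated correlation). Of the neuronal genes 2 of 8 rose (4 adjusted over the list alone), MAP2 by 1.40 (SE 0.097), with a median of 0.51 (camera adjusted p = 0.00598, and adjusted p = 0.186 with an estimated correlation). Of the interferon genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), STAT2 rising by 0.47 (SE 0.092), with a median of 0.25 (camera adjusted p = 0.0138, and adjusted p = 0.186 with an estimated correlation).

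**Figure D4:**
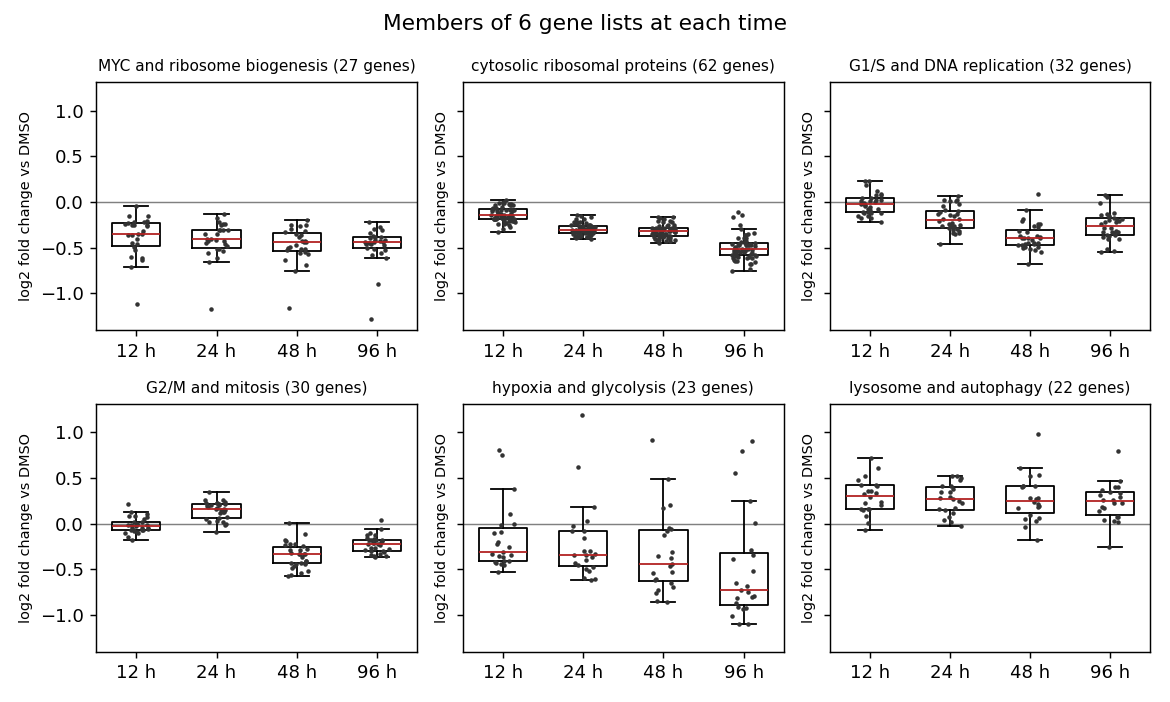
Log2 fold change against DMSO (vertical axis) of each measured member (points) of 6 gene lists at 12, 24, 48 and 96 h; boxes span the quartiles with the median as a red line, and whiskers reach to 1.5 times the interquartile range. Ribosomal protein medians move from -0.145 at 12 h to -0.51 at 96 h and hypoxia and glycolysis medians from -0.31 to -0.73, while G2/M medians go from 0.16 at 24 h to -0.33 at 48 h.

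Genes of cell identity moved in both directions at 96 h without a call of their list. Of 22 synovial sarcoma associated genes 5 rose and 3 fell (6 and 3 adjusted over the list alone), with a median of 0.099 (camera adjusted p = 0.388). The receptor FGFR2 rose by 0.65 (SE 0.088) and the corepressor TLE4 by 0.53 (SE 0.092), while UNCX fell by 1.11 (SE 0.16). Of 35 homeobox and T-box factors 4 rose and 6 fell (4 and 7 adjusted over the list alone), with a median of -0.043 (adjusted p = 0.762). HOXB4 rose by 0.76 (SE 0.11) and LHX4 by 0.87 (SE 0.16), and EN2 and TBX2 fell by 0.58 and 0.61 (SE 0.097 and 0.11). Of 31 Polycomb genes 4 rose and 3 fell (5 and 5 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.741); PCGF5 fell by 0.69 (SE 0.13) and RYBP rose by 0.41 (SE 0.093). Of 28 extracellular matrix and mesenchymal genes 5 rose and 5 fell (7 and 7 adjusted over the list alone), COL5A2 rising by 0.61 (SE 0.099) and PDGFRA falling by 1.07 (SE 0.11). Their median was 0.00057 and their mean -0.062, with a camera direction of lower (adjusted p = 0.856).

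The Wnt, FGF and ERK, Notch and Hedgehog, cholesterol, stress response, heat shock, p53 and CDK inhibitor lists were uncalled at 96 h. Of 18 Wnt genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), LEF1 falling by 0.46 (SE 0.089), with a median of 0.13 (camera adjusted p = 0.284). Of 23 FGF and ERK targets 4 rose and 1 fell (5 and 5 adjusted over the list alone), the phosphatase DUSP4 rising by 0.94 (SE 0.18) and ETV4 falling by 0.52 (SE 0.11). Their median was -0.0052 and their mean 0.095, with a camera direction of higher (adjusted p = 0.478). Of 17 Notch and Hedgehog targets 2 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.43). Of 24 cholesterol genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), TM7SF2 rising by 1.31 (SE 0.16) and CYP51A1 falling by 0.96 (SE 0.18), with a median of -0.097 (adjusted p = 0.31). Of 23 stress response genes 3 fell (3 adjusted over the list alone), DDIT4 with the serine synthesis enzymes PSAT1 and PHGDH (-0.56 and -0.52, SE 0.11 each), with a median of -0.055 (adjusted p = 0.257). Of 18 heat shock genes 1 rose and 2 fell (1 and 3 adjusted over the list alone), HSPD1 falling by 0.55 (SE 0.087), with a median of -0.14 (adjusted p = 0.43). Of 21 p53 targets 2 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.019 (adjusted p = 0.469), and of 12 CDK inhibitors and D-type cyclins 1 rose and 1 fell (1 and 1 adjusted over the list alone). The median of the latter was 0.0022 (adjusted p = 0.857), and fry gave them the direction lower.

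Mitochondrially encoded transcripts, 3 higher and 1 lower of 13 at 96 h (4 and 1 adjusted over the list alone, and 0 called by DESeq2), had a median of 0.165 (camera adjusted p = 0.247). They took 7.38% of the counts in replicate 1 and 10.9% in replicate 2 of 96 h, and MT-ND5, called higher, had 1 library at 96 h that did not lie above both DMSO libraries. Of 6 osteochondrogenic genes 2 rose (2 higher and 1 lower adjusted over the list alone), COMP by 1.09 (SE 0.24), with a median of 0.21 (adjusted p = 0.208). Of 7 adipogenic genes 2 fell (2 adjusted over the list alone), SCD among them, with a median of -0.135 (adjusted p = 0.101). Among 14 BCL2 family genes (median 0.016, adjusted p = 0.8) and 3 cancer-testis antigens (median -0.0080 and mean 0.0040, adjusted p = 0.949) edgeR, DESeq2 and limma-voom called 0 and 0 had an unadjusted p under 0.05. Among 13 MHC class I genes (median 0.26, adjusted p = 0.178) edgeR called 0, with 3 at an unadjusted p under 0.05 and 1 called by DESeq2 and by limma-voom. Among 4 inflammatory factors (median 0.305, adjusted p = 0.155) edgeR, DESeq2 and limma-voom called 0, with 1 at an unadjusted p under 0.05. Adjusted over each of these 4 lists alone, 0 passed. Markers of other lineages were scarce: 2 myogenic, 1 endothelial and 1 leukocyte gene were measured, too few for camera, and 0 of them were called at 96 h by edgeR, DESeq2 or limma-voom, adjusted over the list alone, or at an unadjusted p under 0.05. Their medians were 0.12, -0.099 and -0.37. At 48 h edgeR and limma-voom, but not DESeq2, called the endothelial gene lower (log2 fold change -0.47), and the leukocyte gene (-0.61) was lower only adjusted over its list alone.

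For some uncalled lists the median, the mean and the camera or fry direction differed in sign. At 12 h these were the respiratory chain and adipogenic lists. At 24 h they were the E3 ligase, cancer-testis, CDK inhibitor, osteochondrogenic and adipogenic lists. At 48 h they were the synovial sarcoma, CDK inhibitor, TGF-beta, Wnt, FGF and ERK, Notch and Hedgehog, and adipogenic lists. Between 12 h and 96 h they were the Polycomb, CDK inhibitor, interferon, MHC class I and stress response lists.

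Of the genes called at 96 h 47.3% were higher, 57.6% with upper-quartile scaling and 60.2% with library size alone. Lower genes came to 577 with the 4 libraries fitted alone and 1891 with the GC offset, and no single library moved either count by more than 1.5-fold. Of the genes chosen for naming, 44 of 93 called at 48 h, 71 of 111 called at 96 h and 21 of 68 called at 96 h against 12 h kept their call without each library, and 49, 40 and 47 lost it without at least 1.

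The times were also compared with each other, without the DMSO libraries entering the contrast and with no DMSO culture known to match either time. Between 12 h and 96 h MUC6 rose 3.85-fold, from 210 ± 11.2 to 811 ± 135 CPM (log2 fold change 1.95, SE 0.11, adjusted p = 9.13e-11), PRR36 5.10-fold (2.35, SE 0.24) and MATN2 2.96-fold (1.57, SE 0.16). CDH23, a cadherin, rose 2.58-fold (1.37, SE 0.12, adjusted p = 2.56e-07), and CDKN1A and MAP2 rose by 0.78 and 0.60 (SE 0.13 and 0.093). The homeobox factor ISL2 fell 2.37-fold (-1.24, SE 0.20), the histone gene H4C2 2.01-fold (-1.004, SE 0.11, adjusted p = 4.84e-06) and SIM2 1.86-fold (-0.90, SE 0.12). PDGFRA fell by 0.66 (SE 0.11) and ENO1 by 0.56 (SE 0.090), and the collagen chain COL5A1 and the Wnt receptor partner LGR5 rose by 0.51 and 0.58 (SE 0.089 and 0.097). edgeR called 391 genes higher and 285 lower at 96 h than at 12 h. Counts fell to 99 and 52 without replicate 1 of 12 h, to 109 and 96 without replicate 2 of 12 h and to 238 higher without replicate 2 of 96 h. Lower genes came to 532 and 531 without replicate 1 or replicate 2 of DMSO, and the GC offset gave 731 and 759.

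By list, 41 of 62 ribosomal protein genes fell from 12 h to 96 h (50 adjusted over the list alone), RPS18 by 0.72 (SE 0.079) and RPL10 by 0.57 (SE 0.077), with a median of -0.39 (camera adjusted p = 7.14e-27, and adjusted p = 0.243 with an estimated correlation). Of the hypoxia and glycolysis genes 9 of 23 fell (14 lower and 1 higher adjusted over the list alone), with a median of -0.385 (camera adjusted p = 1.41e-06, and adjusted p = 0.258 with an estimated correlation). Of the G1/S genes 6 of 32 fell (13 adjusted over the list alone; median -0.235, camera adjusted p = 3.94e-08, and adjusted p = 0.273 with an estimated correlation). Of the G2/M genes 1 of 30 fell (10 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.21e-06, and adjusted p = 0.232 with an estimated correlation). Of the respiratory chain genes 4 of 37 fell (17 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 5.13e-08, and adjusted p = 0.232 with an estimated correlation). Of the Wnt genes 5 of 18 rose (11 adjusted over the list alone), LGR5 among them, with a median of 0.29 (camera adjusted p = 1.21e-06, and adjusted p = 0.232 with an estimated correlation). Of the mitochondrially encoded transcripts 6 of 13 rose (11 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 8.99e-05, and adjusted p = 0.427 with an estimated correlation). MT-ND3 rose by 0.65 (SE 0.11), and the overlapping MT-ATP8 and MT-ATP6 by 0.85 and 0.80 (SE 0.12 and 0.13). Without replicate 2 of 96 h their log2 fold changes were 0.41, 0.55 and 0.38, still called. The mitochondrial shares of 7.38% and 10.9% in the 96 h replicates stood against 6.79% and 6.97% at 12 h.

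Other lists were called between 12 h and 96 h as well. The FGF and ERK list had 2 of 23 higher (5 adjusted over the list alone; median 0.15, camera adjusted p = 0.001, and adjusted p = 0.243 with an estimated correlation). The neuronal list had 2 of 8 higher (2 adjusted over the list alone; median 0.45, camera adjusted p = 0.0013, and adjusted p = 0.232 with an estimated correlation). The TGF-beta, YAP and serum response list had 1 of 19 higher (2 adjusted over the list alone and 0 with DESeq2), with a median of 0.14 (camera adjusted p = 0.0269, and adjusted p = 0.443 with an estimated correlation). The BRD family and BET response list had 2 higher and 1 lower of 14 (5 and 1 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00831, and adjusted p = 0.427 with an estimated correlation). The synovial sarcoma list had 4 higher and 2 lower of 22 (5 and 2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0279, and adjusted p = 0.443 with an estimated correlation). In 3 called lists edgeR, DESeq2 and limma-voom called 0 members. The epithelial list (median 0.60, camera adjusted p = 0.000816, and adjusted p = 0.243 with an estimated correlation) had 4 of 8 at an unadjusted p under 0.05 and 4 higher adjusted over the list alone. The MYC and ribosome biogenesis list (median -0.13, adjusted p = 0.0388, and adjusted p = 0.427 with an estimated correlation) had 5 of 27 and 0. The adipogenic list (median -0.30, adjusted p = 0.0373, and adjusted p = 0.258 with an estimated correlation) had 2 of 7 and 2 lower.

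Between successive times fewer genes differed. At 24 h against 12 h edgeR called 0 genes, with 589 at an unadjusted p under 0.05 where chance alone gives 819. DESeq2 called 1 higher, limma-voom 0, and the 4 libraries fitted alone gave 37 higher and 41 lower. The 12 h and 24 h replicates differed less than those of DMSO and 96 h, while the test pools the spread of all groups. The 0 calls therefore do not show that no gene changed. At 48 h against 24 h edgeR called 32 higher and 92 lower genes. Of the 30 G2/M genes 20 fell (28 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 1.15e-33, and adjusted p = 0.0254 with an estimated correlation). From 12 h to 24 h the same list had a median of 0.15 (camera adjusted p = 1.48e-09, and adjusted p = 0.416 with an estimated correlation). These list tests between successive times were added after the data were seen. Without replicate 1 or 2 of 24 h the counts at 48 h against 24 h came to 2 and 0, or 3 and 8, and without replicate 1 or 2 of 48 h to 1 and 1, or 1 and 0. They came to 20 and 54 without either replicate of 12 h, to 67 and 155 or 65 and 155 without replicate 1 or 2 of DMSO, and to 61 higher or 57 and 144 without replicate 1 or 2 of 96 h.

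At 96 h against 48 h edgeR called 3 genes higher and 3 lower, named here after their values were seen. SCD, uncalled at 48 h against DMSO (2071 ± 212 CPM against 2268 ± 64.9, adjusted p = 0.439), fell by 0.78 (SE 0.094, adjusted p = 0.000316), RRAGD by 0.67 and the nuclear RNA NEAT1 by 0.70, while AMOTL2, CYFIP2 and CDH23 rose by 0.54, 1.37 and 0.62 (adjusted p = 0.0456 for these 5). The counts came to 78 higher and 40 lower without replicate 1 of 96 h, 9 and 10 or 26 and 19 without replicate 1 or 2 of DMSO, and 0 and 5 without replicate 2 of 96 h. They came to 0 and 1 without either replicate of 12 h or replicate 2 of 48 h, and to 0 higher without either replicate of 24 h or replicate 1 of 48 h. In the edgeR fit to all libraries 1507 genes had an unadjusted p under 0.05, DESeq2 called 8 and 13, and limma-voom 0 and 1. camera called 11 of 33 lists at the preset correlation and 0 with an estimated correlation. Among them were G1/S genes (median 0.11, adjusted p = 0.000736; 0.478 with an estimated correlation), G2/M genes (0.093, 0.00243; 0.462) and ribosomal protein genes (-0.19, 1.01e-14; 0.462). edgeR called 0 members of these 3 lists. Adjusted over each list alone, 1 G1/S gene and 4 G2/M genes were higher and 25 ribosomal protein genes lower.

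Calls against DMSO overlapped between times. Of 2725 genes called at any time, 516 were first called at 12 h, 250 at 24 h, 998 at 48 h and 961 at 96 h, and 98 were higher and 167 lower at all 4 times. A first call marks a threshold passed and not a change from the time before. Direct tests called 0 genes at 24 h against 12 h, 124 at 48 h against 24 h and 6 at 96 h against 48 h. At 12 h and 96 h 367 genes were called in the same direction, and at 48 h and 96 h 1091. Independent calls would give 12.3 higher and 21.6 lower genes for the first pair and 40.3 and 60.5 for the second. Every comparison shares the DMSO libraries, and part of the excess may come from them; they were not split, as each part would hold 1 library. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.576 between 12 h and 96 h and at 0.721 between 48 h and 96 h. Over 20 draws of simulated data with the same sharing and no treatment effect they correlated at 0.463 and 0.456 on average. The covariance was 0.0807 and 0.114, against 0.026 and 0.0259 in the simulated data. These draws gave all groups the same dispersion for each gene and no GC trend. The real DMSO replicates differed more than those at 12, 24 and 48 h, so the simulated values may be too low. Of the 201 genes higher at 12 h, 153 were called higher at 96 h, and of the 315 lower, 214 were called lower. Opposite calls were rare and are named after their values were seen. NPIPB5 fell at 12 h (-0.77, adjusted p = 0.0301) and rose at 96 h (0.55, adjusted p = 0.0402), and HDAC5 rose at 12 h (0.55, adjusted p = 0.00266) and fell at 96 h (-0.32, adjusted p = 0.0498). MUC2 fell at 12 h (-0.78, adjusted p = 0.022) and rose at 48 h (0.52, adjusted p = 0.0449), and CA4 fell at 24 h (-0.97, adjusted p = 0.0474) and rose at 96 h (0.97, adjusted p = 0.00296). A joint edgeR test of the 4 times against DMSO called 1786 genes, and 3351 with the GC offset.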

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

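All tests of explanations in this part were chosen after the results they address had been seen. The comparison of 96 h with 12 h itself was set before the data were examined. Groups of 2 libraries allow no test for a library that stands apart within its group.

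Between 12 h and 96 h of WA-68 edgeR called 391 genes higher and 285 lower at 96 h by a test of the difference between the times, which has no DMSO culture of known matching time. Without replicate 1 of 12 h these counts were 99 and 52, and without replicate 2 of 12 h 109 and 96. They were 238 higher genes without replicate 2 of 96 h, and 532 and 531 lower genes without replicate 1 and replicate 2 of DMSO.

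Genes were ranked here among called genes with a symbol, a mean of at least 5 CPM and both 96 h libraries beyond both 12 h libraries. That separation was thus a condition of the choice and not a result. The largest differences upward were those of PRR36 (log2 difference 2.35), MUC6 (1.95), MATN2 (1.57), MEGF11 (1.37) and CDH23 (1.37). The largest downward were those of ISL2 (-1.24), NR4A1 (-1.16), H4C2 (-1.004), TMEM160 (-0.98) and DDIT4 (-0.98). The calls of MEGF11, NR4A1 and DDIT4 were lost without replicate 2 of 12 h (adjusted p = 0.0788, 0.212 and 0.0585), and that of TMEM160 without replicate 1 of 12 h (0.113).

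For 5 gene lists camera called the difference between 12 h and 96 h, and their medians against DMSO had opposite signs at these times. The median of the BRD family list was only -0.0431 at 12 h and was 0.0222 with library size as the only scaling, so its sign there is not settled. Nor is that of the adipogenic list at 12 h, with a median of 0.166 but 2 members called lower, 0 higher and a fry direction of lower. The sign of the mitochondrially encoded list at 96 h is not settled either. Mitochondrial transcripts took 7.38% of the counts in replicate 1 and 10.9% in replicate 2 of 96 h, against 7.81% and 8.12% in DMSO. camera did not call the synovial sarcoma list against DMSO at 12 h or 96 h, nor the Wnt list at 96 h. Members of both lists were called in both directions at 96 h, so a reversal against DMSO is not settled for these lists either. The median log2 differences of the 5 lists between 12 h and 96 h were 0.156 for the BRD family and BET response genes, 0.169 for synovial sarcoma associated genes, 0.39 for mitochondrially encoded transcripts, 0.289 for Wnt targets and inhibitors, and -0.301 for adipogenic genes. With an estimated correlation the adjusted p was 0.427, 0.443, 0.427, 0.232 and 0.258 in that order.

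Ribosomal protein transcripts were lower at 96 h, with 57 of 62 called and a median log2 fold change of -0.51 against a median SE of 0.088. The tables argue against the replicate 2 libraries of DMSO and of 96 h as the whole cause, since without both the median was -0.578. With an offset for GC content, the trend that set DMSO replicate 2 apart, the median was -0.527. With an offset for transcript length it was -0.512. GC content and length were those of the longest annotated transcript, with a median length of 1917 bases for these genes. Their median GC content was 49.4%, against 48.4% for all genes tested, so the GC offset could move the list only a little. A trend with the GC content or the length of the transcripts present is therefore not settled. A lower output of ribosomal protein transcripts after long exposure to WA-68 may be the reason. GC content and transcript length, reads shared with processed pseudogenes and time in culture, with no harvest time known for DMSO, stay open.

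Of 23 hypoxia and glycolysis genes 5, 7, 11 and 17 were called lower and 1 higher at 12, 24, 48 and 96 h against DMSO, and the camera call of the list was lost at each time with an estimated correlation (adjusted p = 0.542, 0.423, 0.41 and 0.251). From 12 h to 96 h their median moved by -0.385 (median SE 0.125, 9 of 23 lower; adjusted p = 0.258 with an estimated correlation). That contrast uses no DMSO library, so by construction an offset of the DMSO cultures cannot enter it. How much such an offset adds to the falls against DMSO is left open by it. With the GC offset the move was -0.355. At 12 h an offset of the DMSO cultures cannot be told apart from an effect of WA-68, since the median moved by only -0.0698 from 12 h to 24 h and the harvest time of DMSO is not in the labels. Time in culture cannot be told apart from WA-68 as the cause of the later move either, because 0 DMSO libraries have a harvest time in the labels.

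The 516 calls at 12 h rest on DMSO libraries that differ from each other with GC content. With the GC offset 516 of the 516 stayed called in the same direction, which argues against that difference as their whole cause. The offset also lowered the coefficient of variation from 7.17% to 5.42% and raised the calls to 1264. A gene with a smaller fold change could therefore stay called. Without DMSO replicate 2, 300 of them stayed called in the same direction. For the others an effect of that library cannot be told apart from the loss of a control. An early response to WA-68 and the harvest time of the DMSO cultures both stay open.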

How the results depend on the processing

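All alternatives here were set before the data were examined except the GC and length offsets and the joint removal of replicate 2 of DMSO and of 96 h. Of the recomputed counts 355 stayed within 1.5 times the reported value and 186 moved further. Of the recomputed values of named genes 10574 kept direction and side of the threshold, 991 lost their call, 33 gained a call, 163 uncalled values changed sign and 0 calls changed direction. RLE factors and the length offset moved no count by more than 1.5 times, nor did upper-quartile factors. Except where the construction shows it (fewer libraries, a stricter or a looser threshold), the cause was not tested. Where a library was left out, the lone library of its group was assumed to vary like the other groups. No strong effect shared by replicate number was seen. Over 10 pairs of groups the correlation of replicate differences ran from -0.123 to 0.186, with 1 above 0.1. The highest was that of DMSO with 96 h, whose replicate 2 libraries stood apart from the others. Whether cultures of the same number were handled together cannot be read from these correlations. Small changes were often missed in simulated data.

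With single libraries left out, counts of higher and lower genes ran from 34 to 266 and 68 to 533 at 12 h, 45 to 321 and 67 to 636 at 24 h, and 256 to 825 and 164 to 1215 at 48 h. They ran from 685 to 1154 and 847 to 1309 at 96 h, 0 to 4 and 0 to 1 at 24 h against 12 h, and 1 to 67 and 0 to 155 at 48 h against 24 h. At 96 h against 48 h they ran from 0 to 78 and 1 to 40, and at 96 h against 12 h from 99 to 585 and 52 to 532.

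With library size as the only scaling lower genes came to 173 at 12 h, 205 at 24 h and 543 at 48 h. It gave 1 higher gene at 24 h against 12 h, 21 higher at 48 h against 24 h, and 0 higher and 1 lower at 96 h against 48 h. With no filter 483 genes were lower at 12 h, and the counts were 10 and 1 at 24 h against 12 h, 69 and 158 at 48 h against 24 h, and 55 and 32 at 96 h against 48 h. The stricter filter, the replicate term and limma-voom each gave 0 and 1 at 96 h against 48 h. With only the 4 libraries compared the counts were 108 and 180 at 24 h, 462 lower at 48 h, 577 lower at 96 h, 37 and 41 at 24 h against 12 h, 163 and 261 at 48 h against 24 h, and 6 and 6 at 96 h against 48 h. DESeq2 gave 120, 123 and 398 higher genes at 12, 24 and 48 h, 1 higher at 24 h against 12 h, 21 higher at 48 h against 24 h, and 8 and 13 at 96 h against 48 h.

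With a log2 fold change of at least 1 the counts were 33 and 37 at 12 h, 39 and 38 at 24 h, 141 and 42 at 48 h, and 210 and 94 at 96 h. Between times they were 2 and 0 at 48 h against 24 h, 1 and 0 at 96 h against 48 h, and 54 and 12 at 96 h against 12 h. At that size 44 genes were shared in direction by 12 and 24 h, 46 by 12 and 48 h, 52 by 12 and 96 h, 56 by 24 and 48 h, 61 by 24 and 96 h and 131 by 48 and 96 h, and 0 were opposite for 12 and 48 h, 12 and 96 h, and 24 and 96 h. With an adjusted p under 0.01 the counts were 66 and 117 at 12 h, 73 and 149 at 24 h, 270 and 373 at 48 h and 542 and 591 at 96 h. Between times they were 7 and 31 at 48 h against 24 h, 0 and 1 at 96 h against 48 h, and 170 and 117 at 96 h against 12 h. glmTreat against 1.5-fold gave 1 and 8 at 12 h, 0 and 11 at 24 h, 24 and 13 at 48 h and 78 and 40 at 96 h. It gave 0 and 0 at 48 h against 24 h and at 96 h against 48 h, and 5 and 0 at 96 h against 12 h.

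camera with an estimated correlation called 0 lists in each of the 4 comparisons with DMSO and at 96 h against 12 h, where the preset correlation gave 9, 10, 10, 11 and 15. fry called 5 lists at 12 h.

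The GC offset lowered the coefficient of variation from 7.17% to 5.42%. It gave 483 and 781 genes at 12 h, 504 and 912 at 24 h, 1628 lower at 48 h, 1891 lower at 96 h, 1 and 1 at 24 h against 12 h, and 104 and 221 at 48 h against 24 h. It gave 30 and 26 at 96 h against 48 h, 731 and 759 at 96 h against 12 h, and 3351 genes in the joint test. Without replicate 2 of DMSO and of 96 h the counts were 489 and 650 at 12 h, 458 and 665 at 24 h, 16 and 8 at 24 h against 12 h, and 168 and 272 at 48 h against 24 h. They were 22 and 35 at 96 h against 48 h, and 471 lower at 96 h against 12 h.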

Other observations

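The tests of neighbouring genes in this part were chosen after their results had been seen, and so were the genes and gene groups named in it. Histone genes, which cells transcribe mainly during DNA replication, were lower from 48 h on. Of 67 measured histone genes edgeR called 2 lower at 24 h, 49 lower and 1 higher at 48 h, and 47 lower and 2 higher at 96 h. Their median log2 fold change was -0.0068 at 12 h, -0.20 at 24 h, -0.58 at 48 h and -0.53 at 96 h, and between 12 h and 96 h 38 fell with a median of -0.52. They took 0.821% and 0.887% of all counts in the DMSO libraries and 0.572% and 0.675% at 96 h. Histone genes are near-identical copies and most of their transcripts lack a poly(A) tail, so counts of single histone genes from a poly(A) library are uncertain.

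Some genes called at 12 h lay next to each other. On chromosome 22 (GRCh38) ZDHHC8BP, LINC01659 and PCAT14, from 23390606 to 23547797, had log2 fold changes of -2.05, -1.29 and -2.59 at 12 h. On chromosome 7, from 80742538 to 83649113, the semaphorins SEMA3C and SEMA3E, the calcium channel subunit CACNA2D1 and the synaptic protein PCLO were higher by 0.63, 0.43, 0.50 and 0.89. On chromosome 10, from 101061841 to 101270148, KAZALD1, the homeobox factor LBX1 and its antisense neighbour LBX1-AS1 had log2 fold changes of -0.68, -1.20 and -1.59. The strand setting of the counts is not given, so the values of overlapping antisense genes are uncertain.

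Neighbouring genes may respond to WA-68 together. This was tested on 11023 pairs of adjacent tested genes that did not overlap and lay less than 500000 bp apart. At 12 h 19 pairs were called in the same direction, where calls permuted within expression deciles gave 6.25 on average and at most 18. At 96 h 191 pairs were, against 103 on average and at most 141 (p = 1e-04 at each time, the smallest that 10000 permutations can give). Pairs called in opposite directions stayed within the permuted range by this permutation test, with 6 against 5.7 at 12 h (permutation p = 0.51) and 93 against 101 at 96 h (permutation p = 0.82). Without the histone genes the counts were 19 at 12 h and 164 at 96 h, against 6.25 and 102 on average. Random placement of calls is thus argued against, while shared regulation and read-through were not separated. The permutation matched expression and not GC content.

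Transcripts that poly(A) selection should largely remove varied between replicates. The mitochondrial ribosomal RNA MT-RNR2 had 146 and 5906 counts in replicates 1 and 2 of 24 h and 2640 and 86 in those of 48 h.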
